A study of Mus musculus with 12 samples.

How the data were processed

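Poly-A enriched, non-stranded, single-end RNA sequencing was deposited for 12 mouse libraries. RNA was extracted with Trizol and cleaned on Qiagen columns, per the labels' protocols. The libraries come from brown adipose tissue (BAT) and inguinal white adipose tissue (IWAT), with 3 libraries in each of 4 groups. WT-NC stands for libraries titled WT and NC, and KI-HFD for libraries titled KI and HFD, whose genotype label reads Adv-CGRPalpha+/-. The series text names animals on a high-fat diet and on normal chow with 3 animals per group. Genotype and diet change together in the titles, so each comparison is of genotype and diet jointly. The replicates are treated as separate animals, which the labels state only through that number per group.

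The deposited values are read counts per gene. Reads were checked with FastQC, aligned with STAR to GRCm38.p5 and counted with HTSeq, per the submitters' processing notes, which give no versions. Each count file holds 55536 genes, and all 55536 identifiers were found in the GENCODE annotation used for names and positions. The BAT files also hold 5 summary tallies of reads without a gene, which were left out. In these tallies 4.99 to 11.6% of BAT reads fell in no gene and 22.7 to 31.6% had no unique alignment. Because the counting did not use strand as far as the notes say, reads of a gene and of an antisense or overlapping partner cannot be told apart. Genes with near-identical copies, such as the haemoglobin and cytosolic ribosomal protein genes, are uncertain for reads without a unique alignment.

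The authors also deposited a table per tissue of KI against WT. It holds a base mean, a signal averaged over normalised counts, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value, per the file headers. DESeq2 is named for this step in the submitters' processing notes. The deposited base means were recomputed from the counts to within 0.1% for 29203 genes in BAT and 30669 genes in IWAT. A single gene of the count files is absent from each of them. Whether the deposited log2 fold changes were shrunken is not stated.

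Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. For each tissue, genes were kept with filterByExpr (minimum count 10), scaled by TMM and tested with edgeR's quasi-likelihood F test in a fit of that tissue's 6 libraries. The difference between tissues was tested as an interaction in a fit of all 12 libraries. P values are two-sided and were adjusted with the Benjamini-Hochberg method, with a threshold of 0.05. Levels are given in CPM (counts scaled to a common library total, after TMM), as mean ± SD with n = 3, and fold changes as log2 of KI-HFD over WT-NC with their standard error (SE).

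The 43 gene lists were written from textbook knowledge, and they, the rule for naming genes and the alternatives below were set before the data were examined. They were tested with camera of limma on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01, and adjusted over the lists tested. Lists with fewer than 5 tested members got no test. Each list was also tested with a correlation estimated from the libraries and with fry, and its members were adjusted over the list alone. With 3 libraries against 3, chance separates the groups completely for 10% of genes.

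The genes named in the text followed a rule that takes up to 10 genes per direction past the threshold in each tissue, with at least 2 CPM on average and no overlap between the groups. Where fewer than 5 genes passed, the 10 genes with the lowest p were taken. The rule adds a fixed set around Calca, its receptors, thermogenic markers, Lep, Adipoq, Adrb3, Xist and Ddx3y, up to 4 members of each list, and the 10 genes with the lowest p for the interaction. Symbols of predicted genes were left out. Genes named outside this rule are described as chosen after their values were seen.

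The fits were tested on simulated data with 200 changed genes drawn from the real means, dispersions and library sizes. For BAT, edgeR recovered 5.97% of genes changed 2-fold, 67.2% of those changed 4-fold and 92.4% of those changed 8-fold, and called 5 unchanged genes. For IWAT these shares were 28.4, 47.8 and 75.8%, with 7 unchanged genes called. For the interaction they were 2.99, 19.4 and 63.6%, with 2 unchanged genes called. There each gene was given the same mean in both depots before the change, though real levels differ between them. These interaction shares may therefore not hold for the real libraries. DESeq2 recovered 14.9, 86.6 and 97.0% in BAT, 52.2, 65.7 and 87.9% in IWAT and 10.4, 44.8 and 81.8% for the interaction. DESeq2 called 37, 44 and 28 unchanged genes in these 3 simulations. A macrophage list lowered 2-fold was recovered by camera in all 3 simulations. Of the lists sharing no member with it, 0 of 37 were called for BAT and 0 of 38 each for IWAT and the interaction. Genes were drawn independently of each other, so these simulations cannot show how often camera calls lists falsely when genes are correlated.

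The alternatives were size factors of DESeq2 (RLE), library totals alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, 1 fit of all 12 libraries, a log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. The file names carry numbers in a lower and a higher series, and the higher series holds 1 WT-NC and 1 KI-HFD library in each tissue. Fits with the number series as a batch term, and of the lower series alone, were chosen after seeing the data. Depth ranged from 17.4 to 23.5 M counts per library, and a count of 0 allows up to 3 counts, which covers counting error only.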

Results

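Gene expression was measured by poly-A RNA sequencing in 2 fat depots of C57BL/6 mice. Brown adipose tissue (BAT) burns lipid for heat and inguinal white adipose tissue (IWAT) stores it under the skin. In each depot 3 WT-NC libraries (wild type, normal chow) were set against 3 KI-HFD libraries (Adv-CGRPalpha+/-, high-fat diet). The series concerns sensory neurons that make the peptide CGRP, so the comparisons ask how the fat of the Adv-CGRPalpha+/- animals on the high-fat diet differs from that of the controls. Genotype and diet change together and cannot be separated. The BAT WT-NC libraries held 17.4, 21.9 and 22.6 M counts and the BAT KI-HFD libraries 20.4, 20.9 and 17.7 M. The IWAT WT-NC libraries held 23.5, 22.0 and 21.9 M counts and the IWAT KI-HFD libraries 22.5, 21.1 and 21.3 M. Between 21148 and 24549 genes had at least 1 count in a library.

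Calca, the gene for CGRP-alpha (chromosome 7, 114631478 to 114636357, minus strand, GRCm38), was near the detection limit in both depots. BAT libraries held 0 to 9 Calca counts and the gene was not tested there, with 0.157 ± 0.201 CPM in WT-NC and 0.232 ± 0.194 CPM in KI-HFD. IWAT libraries held 6 to 25 Calca counts, with 0.794 ± 0.366 CPM in WT-NC and 0.643 ± 0.373 CPM in KI-HFD. Its log2 fold change in IWAT was -0.30 (SE 0.62, edgeR quasi-likelihood adjusted p = 0.885), and it turned to 0.04 when WT-NC replicate 2 or KI-HFD replicate 1 was left out. The neurons that express Calca have their cell bodies outside fat, so these counts check no library's genotype. Calcb, the gene for CGRP-beta, had 0 counts in every BAT library and at most 1 in IWAT. The Y-linked gene Ddx3y was present in every library, at 54.6 to 121 CPM, and Xist had at most 4 counts.

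In BAT, 7 genes, among them chemokine genes, were lower in KI-HFD than in WT-NC and 0 were higher (edgeR quasi-likelihood). Macrophage lists were lower and lists for mitochondria, lipid metabolism and thermogenesis higher by camera with its preset correlation, and no list was called with an estimated correlation (smallest adjusted p 0.427). Ccl2, a chemokine that attracts monocytes, had 17.7 ± 1.29 CPM in WT-NC and 1.64 ± 0.699 CPM in KI-HFD, a 10.7-fold lower level. Its neighbour Ccl7 (chromosome 11, 82045712 to 82047525) had 14.1 ± 2.28 and 1.52 ± 0.414 CPM, 9.24-fold lower. Spp1, the gene for osteopontin, had 9.60 ± 2.26 and 0.850 ± 0.194 CPM, 11.2-fold lower. Gdf15, a stress-induced hormone gene, had 19.0 ± 4.31 and 2.27 ± 0.576 CPM, 8.34-fold lower.

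These 4 genes and Rgs1, Adam8 and Ccl9 were the only 7 of 15726 genes past the threshold in BAT, and 0 genes were higher. Each had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0466, and all 3 KI-HFD libraries lay below all 3 WT-NC libraries. Rgs1, a regulator of G protein signalling in leukocytes, fell by 4.34 on the log2 scale (SE 0.50), from 6.31 ± 1.55 to 0.309 ± 0.137 CPM. Adam8, a leukocyte metalloprotease gene, fell by 3.62 (SE 0.41), from 23.9 ± 8.67 to 1.93 ± 0.711 CPM. The chemokine gene Ccl9 fell by 2.70 (SE 0.31), from 41.2 ± 13.4 to 6.34 ± 1.01 CPM. Ccl2 (chromosome 11, 82035571 to 82037453) fell by 3.42 (SE 0.38), Ccl7 by 3.21 (SE 0.33), Spp1 by 3.48 (SE 0.37) and Gdf15 by 3.06 (SE 0.33). The 7 calls are close to the threshold: edgeR made 0 calls with RLE size factors (smallest adjusted p 0.0512), with library totals (0.0504), with the number series as a batch term (0.0805), with all 12 libraries in 1 fit (0.0776), and by limma-voom (0.140). The fold changes stayed about as large in these 5 fits, from -4.48 to -4.31 for Rgs1 and from -3.54 to -3.40 for Ccl2. With the batch term Gdf15 had -3.06 (SE 0.298, against 0.330 without it) and an F of 106 against 86.2, while its p rose from 1.25e-05 to 2.02e-05, since the term leaves fewer residual degrees of freedom. Leaving out single libraries moved the adjusted p of the 7 genes to between 0.0524 and 0.264, the highest without KI-HFD replicate 2. Without WT-NC replicate 3 edgeR made 2 calls, neither among the 7, within the lower number series alone 1 call, not among the 7, and 0 calls without any of the other 5 BAT libraries, while DESeq2 made 244 calls (60 higher, 184 lower), with all 7 among them, and 1244 genes had an unadjusted edgeR p under 0.05.

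**Figure D1:**
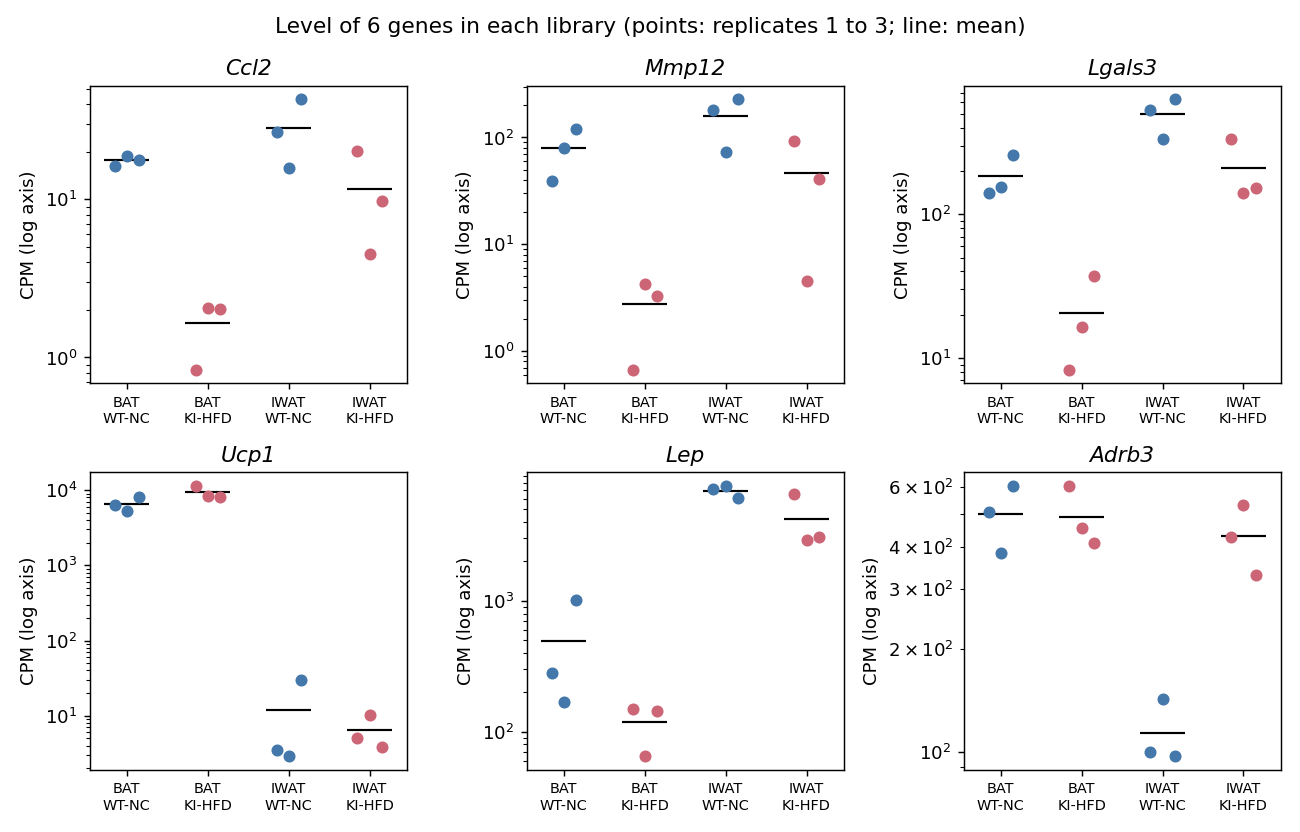
CPM (log axis) of 6 genes in each of the 12 libraries; points are libraries, lines are group means of 3. Ccl2, Mmp12 and Lgals3 were lower in all 3 BAT KI-HFD libraries than in all 3 BAT WT-NC libraries, and Adrb3 was higher in all 3 IWAT KI-HFD libraries (mean 430 CPM) than in IWAT WT-NC (mean 113 CPM).

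Among the lists, transcripts known from fat that expands on high-fat feeding stood lowest in BAT. Of 17 tested members 16 were below 0, with a median log2 fold change of -2.31, and 13 separated the groups completely, all with KI-HFD below WT-NC, where chance separates 10% counting both directions. Mmp12, a macrophage elastase gene, had 79.8 ± 40.4 CPM in WT-NC and 2.75 ± 1.86 CPM in KI-HFD, and Lgals3, the gene for galectin-3, had 183 ± 63.4 and 20.7 ± 15 CPM. Macrophage and monocyte transcripts had a median of -1.74, with 18 of 20 members below 0, among them Ctss (94.9 ± 47.2 and 16.7 ± 4.94 CPM), Cd68 (60.8 ± 35.0 and 11.6 ± 3.49 CPM) and Itgax (7.77 ± 4.46 and 0.601 ± 0.611 CPM). Inflammatory cytokine and acute-phase transcripts had a median of -1.33, with 13 of 15 below 0, among them Ptx3 (7.81 ± 3.66 and 1.34 ± 0.224 CPM). The camera adjusted p was 1.01e-16 for the expansion list, 4.32e-11 for macrophages and 8.73e-12 for cytokines, and 0.427 for each with an estimated correlation. The expansion list shares Itgax with the macrophage list and Ccl2 with the cytokine list, and holds further macrophage genes such as Mmp12. These lists are therefore not separate signals. KI-HFD lay below WT-NC completely for 7 macrophage and 9 cytokine members. Adjusted over the list alone, 14 expansion, 14 macrophage and 7 cytokine members fell, against 2, 0 and 2 adjusted over all genes. The summed macrophage transcripts stood at 461, 1099 and 1888 CPM in the WT-NC libraries and at 292, 311 and 368 CPM in the KI-HFD libraries.

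Other lists that were lower in BAT KI-HFD covered connective tissue, lymphocytes and dividing cells. All 24 collagen and extracellular matrix members were below 0 (median -0.86, adjusted p = 5.04e-07), with Timp1, a protease inhibitor gene, at 4.89 ± 1.78 and 0.697 ± 0.527 CPM, and 4 members fell when adjusted over the list alone. All 17 cell cycle members were below 0 (median -0.92, adjusted p = 7.27e-09), with Cenpe at 3.25 ± 0.211 and 1.12 ± 0.360 CPM. Fibroblast and progenitor transcripts had a median of -0.90 (adjusted p = 0.000139), interferon response transcripts -0.52 (1.24e-05) and B and plasma cell transcripts -0.98 (0.000344). T and natural killer cell transcripts had a median of -0.56 (0.000449), class II antigen presentation -0.98 (0.00165), erythroid transcripts -0.79 (0.0063) and immediate early transcripts -0.35 (0.000893). These adjusted p are from camera, and with an estimated correlation each list had 0.427 except erythroid transcripts with 0.472. KI-HFD lay below WT-NC completely for 5 of 24 collagen, 5 of 17 cell cycle, 3 of 16 fibroblast and 5 of 18 interferon members. It did so for 5 of 12 B cell, 3 of 12 T cell and 7 of 15 immediate early members, and for 0 of 7 class II and 0 of 8 erythroid members. All complete separations in these lists had this direction, where chance separates 10% counting both directions. Adjusted over the list alone, 1 immediate early member fell, and 0 members of the other lists of this paragraph besides the collagens. Within the lower number series the calls for T cells (0.121), class II (0.293) and interferon (0.132) were lost. Leaving out KI-HFD replicate 2 ended the calls for T cells (0.0531), erythroid (0.63) and immediate early transcripts (0.197). Leaving out WT-NC replicate 3 ended those for class II (0.166) and erythroid transcripts (0.0567), and leaving out WT-NC replicate 1 those for erythroid (0.0904) and immediate early transcripts (0.0644).

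Metabolic lists moved the other way in BAT. Of 25 thermogenesis members 24 were above 0 (median 0.49, camera adjusted p = 2.01e-07). Slc27a2, a fatty acid transport and activation gene, had 89.3 ± 18.9 CPM in WT-NC and 317 ± 43.7 CPM in KI-HFD, the potassium channel gene Kcnk3 145 ± 23.8 and 341 ± 52.2 CPM, and Elovl3, a fatty acid elongase gene, 130 ± 72.5 and 390 ± 67.2 CPM. Branched-chain amino acid catabolism had all 15 members above 0 (median 0.72, 1.19e-07), fatty acid oxidation 22 of 23 (0.61, 1.75e-08) and the tricarboxylic acid cycle all 14 (0.55, 5.58e-05). Nuclear-encoded oxidative phosphorylation subunits were above 0 for 74 of 78 members (0.34, 4.42e-09) and mitochondrial ribosomal proteins for 70 of 74 (0.31, 4.02e-09). Triglyceride synthesis had a median of 0.48 (0.000264), de novo lipogenesis 0.38 (0.000278), white adipocyte genes 0.30 (0.0352), lipolysis and fatty acid uptake 0.22 (0.0078) and cholesterol biosynthesis 0.14 (0.0267). With an estimated correlation the adjusted p was 0.427 for these lists, 0.433 for the tricarboxylic acid cycle and 0.629 for cholesterol biosynthesis. Most members overlapped between the groups: KI-HFD lay above WT-NC completely for 8 of 25 thermogenesis, 2 of 15 branched-chain, 2 of 23 fatty acid oxidation, 2 of 14 tricarboxylic acid cycle, 14 of 78 oxidative phosphorylation and 22 of 74 mitochondrial ribosomal members, where chance separates 10% counting both directions. The same held for 5 of 18 triglyceride synthesis, 4 of 19 lipogenesis, 3 of 16 white adipocyte, 2 of 16 lipolysis and 3 of 22 cholesterol members, while 1 mitochondrial ribosomal and 1 white adipocyte member lay completely below. Adjusted over the list alone, 2 thermogenesis members and 1 each of branched-chain amino acid catabolism, cholesterol biosynthesis and white adipocyte genes rose, and 0 adjusted over all genes. The cholesterol call was lost without WT-NC replicate 1 (0.405), WT-NC replicate 2 (0.278) or KI-HFD replicate 1 (0.44), and the lipolysis call without WT-NC replicate 2 (0.152). The white adipocyte call was lost without WT-NC replicate 1 (0.0604), WT-NC replicate 2 (0.278) or KI-HFD replicate 3 (0.27), with the number series as a batch term (0.0585) and with the replicate number as a block (0.0901).

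Individual thermogenic and adipocyte genes in BAT did not pass the edgeR test. Ucp1, the uncoupling protein gene that makes brown fat release heat, had 6567 ± 1398 CPM in WT-NC and 9314 ± 1809 CPM in KI-HFD (log2 fold change 0.50, adjusted p = 0.837). Cidea had 2015 ± 535 and 3407 ± 361 CPM, Ppargc1a 73.8 ± 24.1 and 107 ± 18.4 CPM, Dio2 16 ± 6.11 and 30.5 ± 18.7 CPM (log2 fold change 0.37 without KI-HFD replicate 1), and Prdm16 36.1 ± 11.2 and 49.8 ± 2.02 CPM. Adipoq had 881 ± 198 and 1282 ± 192 CPM, and the beta-3 adrenergic receptor gene Adrb3 499 ± 110 and 490 ± 101 CPM. Lep, the leptin gene, had 489 ± 463 and 119 ± 46.9 CPM (log2 fold change -2.04, SE 0.67, edgeR adjusted p = 0.491, DESeq2 adjusted p = 0.0174), and 1 library, WT-NC replicate 3 with 1020 CPM, set most of the WT-NC mean, so that the log2 fold change was -0.90 without it. Elovl3 had a log2 fold change of 1.58 (SE 0.44, edgeR adjusted p = 0.389, DESeq2 adjusted p = 0.0172). The CGRP receptor genes Calcrl (20.1 ± 11 and 15.5 ± 2.30 CPM) and Ramp1 (18.3 ± 16.3 and 7.19 ± 4.09 CPM, log2 fold change -0.40 without WT-NC replicate 2) did not pass, nor did Ramp2 (87.9 ± 35.7 and 59.0 ± 31.5 CPM), Ramp3 (3.73 ± 0.541 and 3.91 ± 1.34 CPM) or Avil, a sensory neuron gene (2.09 ± 1.82 and 2.57 ± 1.64 CPM).

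Skeletal muscle transcripts varied most between BAT libraries. All 18 were below 0 (median -1.74), with a camera adjusted p of 0.552. The summed transcripts ran from 646 CPM in WT-NC replicate 3 to 77309 CPM in WT-NC replicate 2 within 1 group. The remaining BAT lists had camera adjusted p of 0.0803 for neutrophils and mast cells (median -0.86) and for smooth muscle (-0.32), 0.0902 for endoplasmic reticulum stress (-0.26), 0.142 for adrenergic signalling (0.31), 0.153 for glycolysis (0.21) and for neuron transcripts (-0.66), and 0.158 for endothelium (-0.13). The calcitonin family had 0.163 (median -0.48), cytosolic ribosomal proteins 0.247 (-0.10), mitochondrially encoded transcripts 0.286 (0.22), and heat shock (-0.18), insulin signalling (0.22) and oxidative stress defence (0.04) 0.291 each. Schwann cells had 0.846 (-0.14), the circadian clock 0.894 (-0.00) and creatine and calcium cycling 0.995 (-0.46), the last with a test direction opposite to its median. The mean of the oxidative stress list and the median and mean of the clock list also lay opposite to the direction of their tests. Epithelial and mammary, mesothelial, and X- and Y-linked lists had too few tested members.

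In IWAT, edgeR called 0 genes (1730 at an unadjusted p under 0.05, 349 called by DESeq2), and with it differences were seen for gene lists alone. By camera with its preset correlation, blood vessel, smooth muscle and matrix lists were lower in KI-HFD and lipogenic, insulin-signalling and amino acid catabolism lists higher, and no list was called with an estimated correlation (smallest adjusted p 0.719). Notch3, a receptor gene of vessel wall cells, had 62.0 ± 13.0 CPM in WT-NC and 23.6 ± 5.82 CPM in KI-HFD, and the pericyte gene Rgs5 had 321 ± 16.5 and 153 ± 40.4 CPM. Adrb3, through which noradrenaline triggers lipolysis in adipocytes, had 113 ± 25.5 and 430 ± 99.4 CPM, 3.80-fold higher. Vnn1, a pantetheinase gene, had 12.2 ± 1.03 and 45.1 ± 5.59 CPM, 3.70-fold higher.

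No single gene passed in IWAT: edgeR quasi-likelihood tests called 0 of 15881 genes, with 1730 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0589, that of Vnn1 (log2 fold change 1.89, SE 0.16). DESeq2 called 349 genes (101 higher, 248 lower) and limma-voom 0. Of the 10 genes with the lowest p, Aspn, a matrix proteoglycan gene, had 78.3 ± 4.82 and 31.3 ± 4.19 CPM, and Spry1, a growth factor signalling inhibitor gene, 75 ± 9.69 and 30.9 ± 2.18 CPM, each with an edgeR adjusted p of 0.0742. St6galnac5, a sialyltransferase gene, had 8.0 ± 0.749 and 35.3 ± 9.31 CPM (0.0742), and Chrdl1, a BMP antagonist gene, 75.8 ± 6.76 and 170 ± 17.7 CPM (0.0855). Tmem252 had 19.9 ± 3.87 and 4.59 ± 0.830 CPM (0.0855), the odorant receptor gene Olfr558 19.8 ± 0.186 and 7.64 ± 0.874 CPM (0.115) and Gucy1a1, a nitric oxide receptor subunit gene, 51.3 ± 2.45 and 21.6 ± 3.87 CPM (0.115). Adrb3 had a log2 fold change of 1.93 (SE 0.24, edgeR adjusted p = 0.106). Ncam2, a cell adhesion gene, was at or near 0 in WT-NC (0.0299 ± 0.0259 CPM) and at 6.49 ± 3.32 CPM in KI-HFD (0.0742). Without KI-HFD replicate 3 edgeR called 10 genes (9 higher, 1 lower), with Vnn1 and Ncam2 at 0.0217, St6galnac5 at 0.0257, Adrb3 at 0.0443 and Aspn at 0.0489, where leaving out single libraries moved the adjusted p of these 5 genes between 0.0217 and 0.598. With library totals as the scaling, Vnn1 and Aspn passed (0.0388).

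Lists for vessels and matrix were lower in IWAT KI-HFD. All 14 endothelial members were below 0 (median -0.74, camera adjusted p = 2.21e-07), and 13 of them separated the groups completely, all with KI-HFD below WT-NC, where chance separates 10% counting both directions. All 12 smooth muscle and pericyte members were below 0 (median -0.87, 2.45e-07), and all 24 collagen and matrix members (median -0.48, 7.73e-07), with Bgn at 272 ± 29.5 and 128 ± 20.3 CPM and Postn at 462 ± 30.1 and 174 ± 89.5 CPM. Skeletal muscle transcripts, a minor part of IWAT counts, had a median of -3.22 (1.17e-07), with summed levels of 115, 426 and 1040 CPM in WT-NC and 170, 84.7 and 166 CPM in KI-HFD. Cell cycle transcripts had a median of -0.80 (4.45e-05), cytokines -0.77 (0.000148), expansion transcripts -0.72 (0.000268), creatine and calcium cycling -0.56 (0.000397), erythroid transcripts -1.12 (0.000968) and macrophages -0.62 (0.00133). Cholesterol biosynthesis had a median of -0.21 (0.0102). The calcitonin family, with a median of -0.27 (0.0124), held Adm, the adrenomedullin gene (43.4 ± 4.92 and 19.8 ± 4.86 CPM), and Ramp2 (124 ± 11.5 and 82.3 ± 1.77 CPM). With an estimated correlation each of these lists had an adjusted p of 0.719. Creatine and calcium cycling holds genes that muscle expresses too, and Atp2a1 (87.0 ± 113 and 7.59 ± 11.3 CPM) and Ckmt2 (2.53 ± 2.06 and 0.218 ± 0.337 CPM) rose with the summed skeletal muscle transcripts from WT-NC replicate 1 to 3, so its call is not shown apart from muscle in the samples. KI-HFD lay below WT-NC completely for 8 of 12 smooth muscle, 4 of 16 skeletal muscle, 3 of 24 collagen, 2 of 17 cell cycle, 3 of 14 cytokine and 1 of 17 expansion members. It did so for 2 of 9 creatine, 1 of 8 erythroid, 1 of 20 macrophage, 3 of 22 cholesterol and 3 of 6 calcitonin members. Adjusted over the list alone, 8 smooth muscle, 3 skeletal muscle, 2 endothelial, 2 collagen, 2 creatine, 2 calcitonin, 1 cell cycle and 1 cytokine members fell, and 0 adjusted over all genes. The macrophage call was lost without WT-NC replicate 3 (0.0728) and within the lower number series (0.144), the calcitonin call without KI-HFD replicate 1 (0.0878), and the cholesterol call without WT-NC replicate 3 (0.199) or KI-HFD replicate 3 (0.0775) and within the lower series (0.466). Within the lower series the collagen call was lost as well (0.052).

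Lists for adipocyte metabolism were higher in IWAT KI-HFD. All 15 branched-chain amino acid catabolism members were above 0 (median 0.54, camera adjusted p = 7.73e-07), with Ivd at 243 ± 51.8 and 460 ± 139 CPM and Bcat2 at 148 ± 29.1 and 288 ± 110 CPM. Insulin signalling had a median of 0.35 (0.00399), with Irs1, an insulin receptor substrate gene, at 10.3 ± 3.12 and 20.4 ± 2.44 CPM. White adipocyte genes had a median of 0.42 (0.00553), with Cfd, the adipsin gene, at 1498 ± 778 and 9717 ± 5863 CPM. De novo lipogenesis had a median of 0.35 (0.0128), with Acacb at 41.3 ± 3.39 and 99.5 ± 48.4 CPM, and the tricarboxylic acid cycle 0.25 (0.0334). With an estimated correlation the adjusted p were 0.719 for the first 2 lists, 0.761 for white adipocyte genes and 0.818 for the last 2. KI-HFD lay above WT-NC completely for 7 of 15 branched-chain, 6 of 16 insulin signalling, 2 of 16 white adipocyte, 8 of 19 lipogenesis and 2 of 14 tricarboxylic acid cycle members, and 2 lipogenesis members lay completely below. Adjusted over the list alone, 6 branched-chain, 4 lipogenesis and 1 white adipocyte members rose, and 0 adjusted over all genes. The tricarboxylic acid cycle call was lost without WT-NC replicate 1 (0.104), WT-NC replicate 3 (0.119), KI-HFD replicate 1 (0.0548) or KI-HFD replicate 2 (0.825). The lipogenesis call was lost without WT-NC replicate 1 (0.0774), KI-HFD replicate 1 (0.0765) or KI-HFD replicate 2 (0.0578), and the white adipocyte call without WT-NC replicate 3 (0.0583), KI-HFD replicate 1 (0.0784) or KI-HFD replicate 2 (0.12).

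Thermogenic genes did not pass with edgeR in IWAT, where all those named here except Prdm16 stood far below their BAT levels. Ucp1 had 12.1 ± 15.4 CPM in WT-NC and 6.4 ± 3.37 CPM in KI-HFD (log2 fold change -0.92, edgeR adjusted p = 0.742), and turned to 1.01 without WT-NC replicate 3 and to 1.26 within the lower number series. Elovl3 had 5.36 ± 2.19 and 0.787 ± 0.559 CPM (log2 fold change -2.76, SE 0.58, edgeR adjusted p = 0.243, DESeq2 adjusted p = 0.000318). Its log2 fold change ran from -3.47 to -2.37 with single libraries left out. Cidea had 21.2 ± 6.80 and 29.7 ± 25.5 CPM and turned to -0.47 on the log2 scale without KI-HFD replicate 2, and Ppargc1a, with 8.54 ± 2.29 and 20.5 ± 15.4 CPM, fell from 1.26 to 0.49 without that library, which had 37.1 CPM. Dio2 had 1.81 ± 0.574 and 0.717 ± 0.554 CPM (log2 fold change -2.16 without KI-HFD replicate 2), and Prdm16 32.5 ± 2.36 and 30.7 ± 11.6 CPM. Lep had 6923 ± 754 and 4197 ± 2077 CPM and Adipoq 3043 ± 572 and 3874 ± 865 CPM. Of the receptor genes, Ramp2 passed with DESeq2 alone (log2 fold change -0.59, DESeq2 adjusted p = 0.019, edgeR adjusted p = 0.242), while Calcrl (23.1 ± 2.55 and 22.0 ± 7.54 CPM) and Ramp1 (5.49 ± 0.595 and 5.64 ± 3.42 CPM) did not pass and Ramp3 was too low to test. Avil had 0.934 ± 0.707 and 2.40 ± 0.458 CPM (log2 fold change 0.86 without WT-NC replicate 1).

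Several lymphocyte genes in IWAT stood out in KI-HFD replicate 3. Cd79a, a B cell receptor gene, had 127 CPM there and at most 2.03 CPM in every other IWAT library, and Ccr7, a lymphocyte homing receptor gene, had 102 CPM there and at most 3.91 CPM elsewhere. The summed B and plasma cell transcripts did not single that library out, with 2454 CPM there and 1136 to 2362 CPM in the others. B and plasma cell transcripts had a median of 3.95 with a camera adjusted p of 0.438, and T and natural killer cell transcripts a median of 1.66 with 0.241 and a test direction opposite to the median. The other IWAT lists had camera adjusted p of 0.0552 for mitochondrially encoded transcripts (median 0.36), 0.059 for interferon response (-0.26), 0.0626 for thermogenesis (-0.14) and 0.0825 for cytosolic ribosomal proteins (0.10). Class II antigen presentation (-0.24), mitochondrial ribosomal proteins (0.05) and oxidative stress defence (0.19) had 0.138 each, heat shock 0.15 (-0.24), fatty acid oxidation 0.154 (0.16) and immediate early transcripts 0.155 (-0.05). Adrenergic signalling had 0.293 (0.14), oxidative phosphorylation 0.321 (0.07), glycolysis 0.424 (-0.13), fibroblasts 0.435 (0.03), and neuron transcripts (0.36) and the clock (0.18) 0.438. Triglyceride synthesis had 0.503 (-0.06), lipolysis 0.526 (-0.08), endoplasmic reticulum stress 0.546 (0.02), Schwann cells 0.863 (0.10) and neutrophils and mast cells 0.896 (0.08). The tests for fibroblasts, Schwann cells and neutrophils and mast cells pointed opposite to their medians. Epithelial, mesothelial, and X- and Y-linked lists were not tested.

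**Figure D2:**
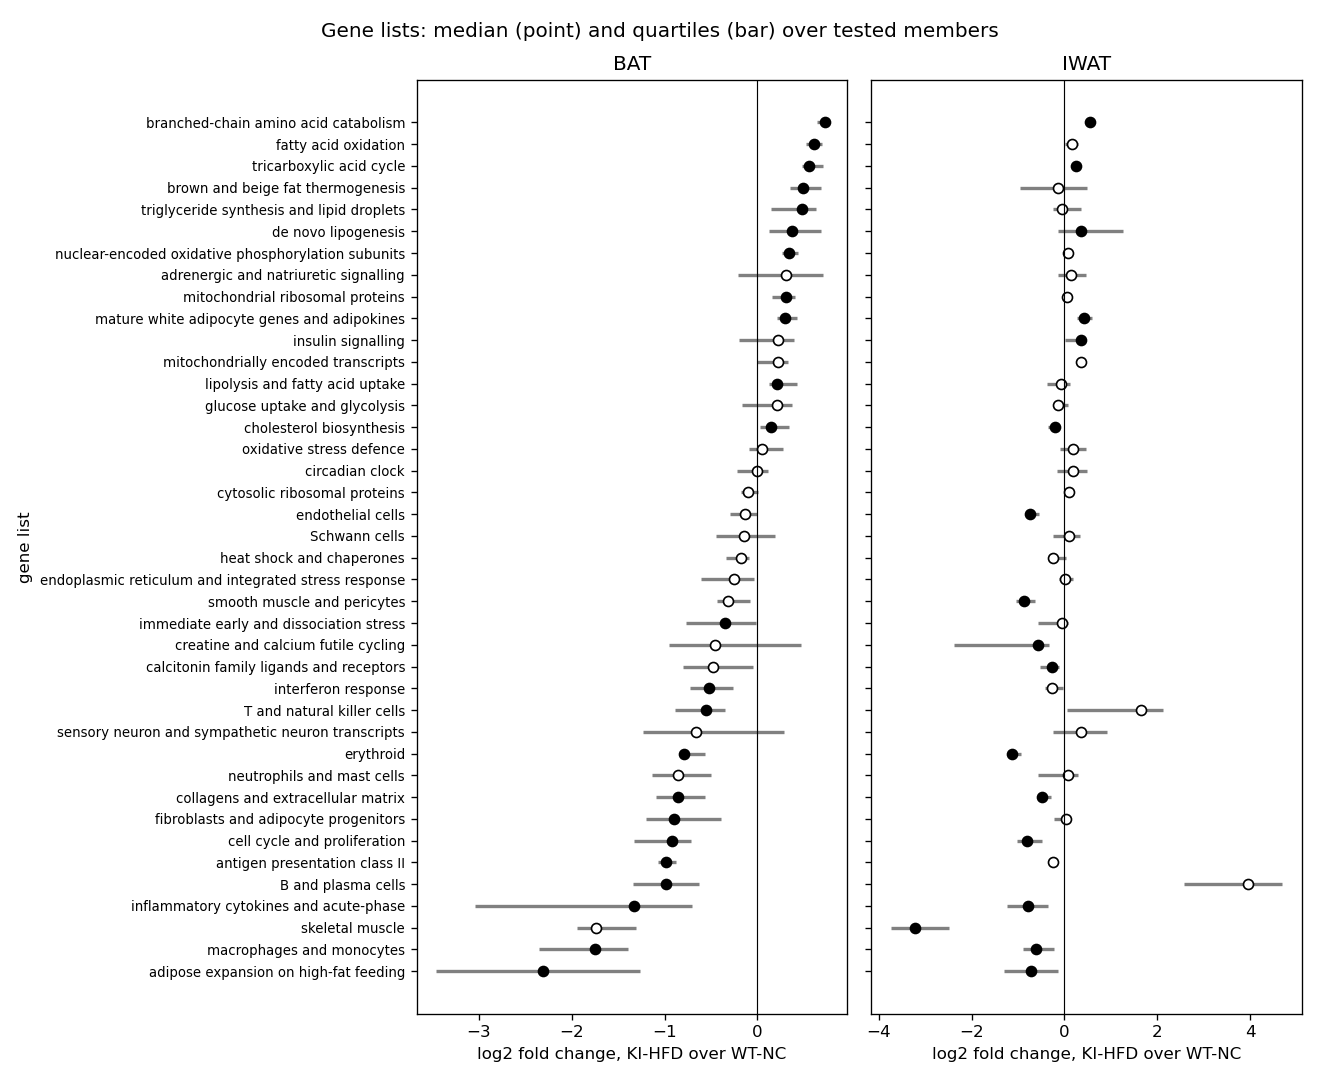
Median log2 fold change of KI-HFD over WT-NC (points) and quartiles (bars) of the tested members of each of the 40 gene lists that camera tested, in BAT and IWAT; filled points have a camera adjusted p under 0.05 with the preset correlation. The expansion list (-2.31) and the macrophage list (-1.74) lie lowest among the filled points in BAT, and branched-chain amino acid catabolism lies highest among them (0.72).

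The 2 depots were compared to ask whether the difference between groups was the same in brown and in white fat. Elovl3 was 3.00-fold higher in BAT KI-HFD and 6.76-fold lower in IWAT KI-HFD, a difference of 4.34 on the log2 scale (SE 0.73). With single libraries left out that difference ran from 3.95 to 5.02. Adrb3 went the other way, with a difference of -1.94 (SE 0.38). Thermogenesis, oxidative phosphorylation and fatty acid oxidation lists stood higher in the BAT comparison than in the IWAT comparison, and expansion and macrophage lists lower. No gene passed the interaction test: edgeR called 0 of 17395 genes, with 831 at an unadjusted p under 0.05 and a smallest adjusted p of 0.463, limma-voom called 0 and DESeq2 25 (13 higher, 12 lower). The other 8 genes with the lowest p had BAT minus IWAT differences of 2.77 (Kcp), 1.66 (Kcnk3), 2.25 (Myrip), 1.73 (Alpl), -1.68 (Ccdc9b), -2.09 (Alcam), -1.94 (Dclk1) and 1.34 (Adam12), each with an edgeR adjusted p of 0.463. Camera called 20 of 40 lists for the interaction (12 higher and 8 lower in BAT), and 0 with an estimated correlation (smallest adjusted p 0.255).

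The lists without an interaction call had camera adjusted p of 0.116 for interferon response (median difference -0.31), 0.126 for immediate early transcripts (-0.30), 0.132 for glycolysis (0.16), and 0.161 for insulin signalling (-0.17) and for branched-chain amino acid catabolism (0.18). Oxidative stress defence had 0.269 (-0.11), neutrophils and mast cells 0.3 (-0.79), collagens 0.36 (-0.35), and the clock (-0.41) and class II antigen presentation (-0.70) 0.368. The cell cycle had 0.579 (-0.26), white adipocyte genes (-0.03) and T and natural killer cells (-2.20) 0.635, and erythroid transcripts 0.644 (0.38). Adrenergic signalling (-0.03), de novo lipogenesis (0.17) and the calcitonin family (0.04) had 0.664, mitochondrially encoded transcripts (-0.02) and Schwann cells (-0.34) 0.85 and heat shock 0.915 (-0.01). For adrenergic signalling the median and mean, and for lipogenesis and the calcitonin family the mean, lay opposite to the test.

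No gene passed in both depots with edgeR, where BAT alone had calls, and the log2 fold changes correlated across the 14654 genes tested in both (Pearson r = 0.319, genes not being independent replicates). With DESeq2, 8 genes were higher in both depots where independent lists would share 0.288. Another 15 were lower in both where they would share 2.72, and 1, Elovl3, went in opposite directions. In the simulations DESeq2 also called 37 unchanged genes for BAT and 44 for IWAT. Another split of the libraries gave 635 DESeq2 calls in BAT and 573 in IWAT, so the shared genes may include false calls. The following genes were chosen after their values were seen. Cfd had DESeq2 log2 fold changes of 2.66 in BAT and 2.70 in IWAT, and Gpx3, a plasma glutathione peroxidase gene, 1.32 and 1.98. Lgals3 had -3.16 and -1.25 and Cd68 -2.41 and -1.18. Numbers in the file names recur between depots, so libraries of both may come from the same animals. The interaction fit with edgeR treats them as independent. With the file number as animal, limma-voom called 0 interaction genes (687 at an unadjusted p under 0.05, smallest adjusted p 0.837), with a consensus correlation of 0.0148, and the lists were not tested with such a term.

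The authors' deposited tables gave more calls in the same directions. They list 247 genes at an adjusted p under 0.05 in BAT (61 higher, 186 lower, of 16794 with an adjusted p) and 335 in IWAT (96 higher, 239 lower, of 15080). Ccl2 in BAT has a deposited log2 fold change of -2.90, and Adrb3 in IWAT one of 1.72. The edgeR calls shared 7 genes with the authors' in BAT and 0 in IWAT, and the DESeq2 calls here shared 242 and 335. All 242 of the authors' BAT calls and all 334 of their IWAT calls that were tested here had the same sign with edgeR. Across genes the deposited and the edgeR log2 fold changes correlated with r = 0.949 in BAT and 0.871 in IWAT, with slopes of 0.628 and 0.480.

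**Figure D3:**
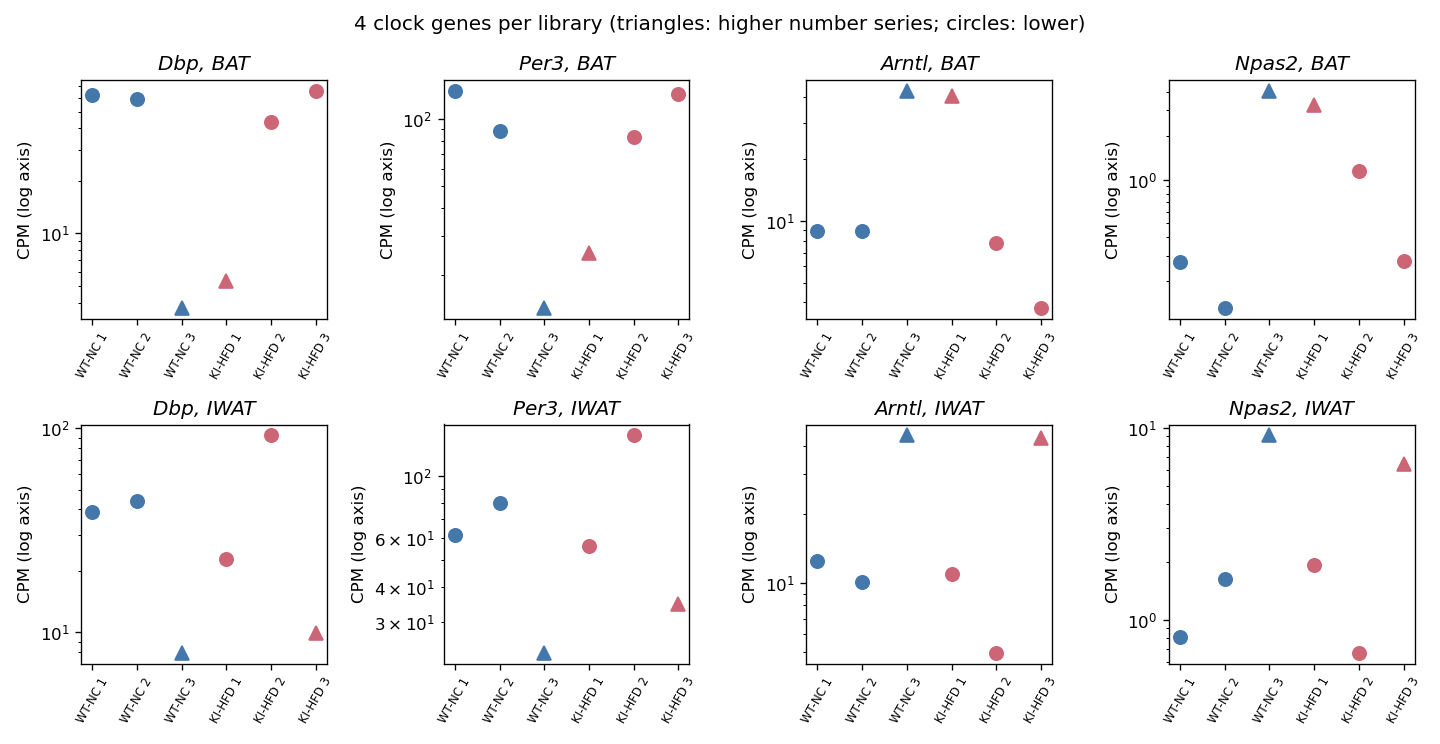
CPM (log axis) of the clock genes Dbp, Per3, Arntl and Npas2 in each BAT and IWAT library; triangles mark the higher number series of the file names, circles the lower. Dbp lies at 3.71 and 5.36 CPM in the higher-series BAT libraries and between 43.7 and 65.7 CPM in the others.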

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

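The tests of explanations for the 3 patterns weighed here were chosen only after the results were seen; the counts over other splits of the libraries were planned.

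The 2 depots differed in 20 gene lists by camera on the interaction, which tests the difference between their group effects. Higher in BAT relative to IWAT were thermogenesis (adjusted p = 5.58e-07), oxidative phosphorylation subunits (5.58e-07), mitochondrial ribosomal proteins (1.15e-06), endothelial cells (1.25e-05), fatty acid oxidation (1.46e-05), cholesterol biosynthesis (0.000238), skeletal muscle (0.000707), smooth muscle (0.000718), triglyceride synthesis (0.000833), creatine and calcium cycling (0.00131), lipolysis (0.00333) and the tricarboxylic acid cycle (0.00812). Lower were expansion transcripts (1.17e-06), macrophages (0.000297), cytokines (0.000877), fibroblasts (0.00333), B and plasma cells (0.00731), endoplasmic reticulum stress (0.0221), neuron transcripts (0.0229) and cytosolic ribosomal proteins (0.0332). With an estimated correlation the adjusted p ran from 0.255 for creatine and calcium cycling to 0.92 for cytosolic ribosomal proteins, so 0 calls held. The creatine and calcium cycling list holds genes that muscle expresses too, such as Atp2a1. Its camera call held with each single library left out (highest adjusted p 0.0242), and its member Alpl had a difference of 1.73. The list was not tested without its muscle-expressed members, so its call is not shown apart from that of skeletal muscle. Without BAT WT-NC replicate 2 the fibroblast call was lost (0.144), and without it or IWAT KI-HFD replicate 3 the lipolysis call (0.102 and 0.112), the latter library also ending triglyceride synthesis (0.0572). The tricarboxylic acid cycle call was lost for 4 libraries, up to 0.322 without BAT KI-HFD replicate 1, and the neuron call for 7, up to 0.134 without that library. The macrophage call was lost without BAT WT-NC replicate 3 (0.235), as were skeletal muscle (0.748) and endoplasmic reticulum stress (0.676). The B cell call turned round without IWAT KI-HFD replicate 3 (0.846), and the cytosolic ribosomal call without BAT WT-NC replicate 1 (0.934) or BAT KI-HFD replicate 1 (0.437). That ribosomal call was also lost without BAT WT-NC replicate 2 (0.278), IWAT WT-NC replicate 3 (0.328) or IWAT KI-HFD replicate 3 (0.514) and with the replicate number as a block (0.0781). The B cell call was also lost without BAT WT-NC replicate 3 (0.0866), BAT KI-HFD replicate 2 (0.144) or IWAT WT-NC replicate 2 (0.0809), the stress call without BAT KI-HFD replicate 3 (0.0793) or IWAT KI-HFD replicate 2 (0.0868), and the neuron call with the number series as a batch term (0.0538). Of 100 splits within both depots, the real one included, 23 gave at least the real 20 lists (highest other 30), so chance cannot be excluded for the lists. For genes the real count is 0, which all 100 splits must reach (highest other 33), so that count says nothing about chance.

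The pattern of lower macrophage, cytokine and expansion transcripts in BAT KI-HFD spans 50 transcripts with a median log2 fold change of -1.76. White fat with the makeup of the IWAT libraries was weighed by IWAT-enriched transcripts. Their mean log2 level in these same BAT libraries had to lie more than 4 below that in IWAT. This choice can lower the measured shares, so they do not exclude such carry-over. In WT-NC replicates 1 and 2 the larger excess over the KI-HFD mean, that of replicate 1, was 0.169% of the IWAT level. The pattern needs a median of 16.9% (lower quartile 1.19%). For WT-NC replicate 3, whose IWAT-enriched transcripts stood at 8.40% of the IWAT level against 2.48 to 4.01% in KI-HFD, the measured share accounted for a median of 12.1% of the excess (upper quartile 20.3%). That library's Spearman correlations with the IWAT libraries were 0.890 to 0.923, against 0.802 to 0.866 for the other BAT libraries. Without it the pattern's median log2 fold change was -1.18. A difference between the number series of the file names is argued against as the whole cause, since each series holds both groups. Within the lower series alone the median was -0.993 (quartiles -2.20 to -0.597, 43 of 49 transcripts below 0). With the series as a batch term the median was -1.64. The macrophage, cytokine and expansion lists kept their preset-correlation calls in each of these fits (highest camera adjusted p 5.65e-06). Those calls add little, since other splits of the BAT libraries gave up to 22 called lists against the real 23. With an estimated correlation 0 lists were called in the fit of all BAT libraries. How much of the size rests on the higher series stays open as untested. So do white fat of another makeup and the genotype and diet of the animals. White fat with the makeup of the IWAT libraries is not excluded either.

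Clock transcripts differed between the number series rather than between the groups: Dbp stood at 3.71 and 5.36 CPM in the higher-series BAT libraries and at 43.7 to 65.7 CPM in the others, and Arntl at 43.1 and 40.7 CPM against 3.74 to 8.92 CPM. The clock list's median absolute series effect lay at percentile 100 of 10000 random lists in each depot. This decides nothing on a batch that shifts transcripts alike, since TMM scaling takes out a common shift. The clock list was also singled out after its split by series was seen. The series difference was not confined to the clock, with 3859 BAT and 1543 IWAT genes at an unadjusted edgeR p under 0.05. Past the threshold for it were 6 genes higher and 1 lower in BAT, and 0 in IWAT. Mitochondrial genes took 4.53 and 5.23% of counts in the higher-series BAT libraries and 6.76 to 14.1% in the others. In IWAT these shares overlapped. Reads in no gene made up 5.30 and 4.99% of tallied reads in the higher-series BAT libraries and 7.64 to 11.6% in the others. Reads without a unique alignment made up 23.0 and 22.7% against 25.5 to 31.6%. The IWAT files hold no such tallies. A batch that shifts transcripts unequally was not tested and stays open. The group comparison is argued against, since its clock effect was at most 0.333 of the series effect. A different clock phase at sampling is a candidate explanation, with 14 of 17 clock transcripts taking the same sign in both depots, while time of day is not in the labels.

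Transcripts that usually rise in expanding fat were lower in the libraries titled HFD by camera with its preset correlation. With an estimated correlation the expansion list was not called (adjusted p 0.427 in BAT and 0.719 in IWAT). In BAT 13 of the 17 expansion transcripts separated the 3 KI-HFD libraries from the 3 WT-NC libraries completely. This argues against a single mislabelled library only if these transcripts follow the true groups, which was not tested. At most 1 separated after an exchange of a library of each group. That count decides nothing, since transcripts separated under the real labels cannot separate after an exchange. Exchanging WT-NC replicate 3 with KI-HFD replicate 3 gave 635 genes with DESeq2 against the real 244. A single mislabelled library stays open in IWAT, where 1 of 17 expansion transcripts separated the groups completely. Grouping KI-HFD replicate 1 with WT-NC replicates 1 and 3 separated 9, the most of any such exchange. Yet that grouping gave 33 genes with DESeq2 against the real 349. Grouping KI-HFD replicate 3 with WT-NC replicates 1 and 3 separated 0 and gave 573 genes. Each such grouping, in either depot, moves a library of each group, so none stands for a single library in the wrong group. Exchanged labels for every library could not be tested, because Calca, the gene in the genotype label, had at most 25 counts in a library and the labels do not say which transcripts the edit changes. The genotype, which changes together with the diet, stays open as an untested biological explanation.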

How the results depend on the processing

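The number-series fits and the lower-series fits were chosen after seeing the data; the other alternatives were planned. The 7 BAT gene calls became 0 with RLE size factors, library totals, limma-voom, all 12 libraries in 1 fit and the number series as a batch term, 1 in the lower series, 11 with the replicate block (5 of them shared), 207 (37 higher, 170 lower) without a filter and 244 (60 higher, 184 lower) with DESeq2, and ranged from 0 to 2 with single libraries left out. The 0 IWAT calls became 2 with library totals, 1 with all 12 libraries, 45 (20 higher, 25 lower) without a filter and 349 (101 higher, 248 lower) with DESeq2, and ranged from 0 to 10 with single libraries left out. The 0 interaction calls became 33 without a filter and 25 with DESeq2. The 0 genes in both depots became 23 with DESeq2, and the overlap with the authors' calls became 242 in BAT and 335 in IWAT. The 23 BAT, 17 IWAT and 20 interaction lists each became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.0634, 0.161 and 0.112). With single libraries left out the list counts ranged from 20 to 25, 13 to 25 and 15 to 24. Same-numbered BAT libraries deviated with r of -0.272, 0.265 and 0.120 and IWAT libraries with -0.111, 0.263 and 0.218. Differently numbered libraries ran from -0.313 to 0.169 in BAT and from -0.318 to 0.150 in IWAT. With 3 libraries per group these values do not settle whether the numbers pair them. The replicate block changed the BAT gene count as above, left IWAT genes at 0 and gave 23, 18 and 19 lists. Named log2 fold changes turned sign for BAT Ramp3 with library totals (-0.055), IWAT Ramp1 with limma-voom (-0.085), the replicate block (-0.114), the batch term (-0.109) and the lower series (-0.493), and IWAT Ucp1 with the batch term (0.020) and in the lower series (1.26). With single libraries left out, ranges crossing 0 were -0.649 to 0.173 for BAT Calcrl, -0.137 to 0.323 for BAT Ramp3, -0.355 to 1.30 for BAT Avil, -0.206 to 0.147 for BAT Adrb3, -0.827 to 0.039 for IWAT Calca, -0.351 to 0.132 for IWAT Calcrl, -0.575 to 0.296 for IWAT Ramp1, -1.44 to 1.01 for IWAT Ucp1, -0.474 to 0.915 for IWAT Cidea, -0.414 to 0.151 for IWAT Prdm16 and -0.205 to 0.080 for IWAT Ddx3y. The interaction of B and plasma cells ran from an adjusted p of 8.63e-06 to 0.846 and that of cytosolic ribosomal proteins from 4.38e-06 to 0.934. In fits other than those leaving out single libraries, 171 BAT, 207 IWAT and 64 interaction values of named genes kept their side of the threshold and direction, 44 BAT values lost their call and 4, 25 and 16 gained one. For called lists 110, 82 and 38 values kept their call and 51, 37 and 42 lost it. Leaving out a library leaves 2 against 3, which lowers power; the cause of the other shifts was not tested. In BAT, edgeR recovered 5.97% of simulated 2-fold changes at this depth and replication.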

Other observations

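The clock transcripts and the counts over other splits were examined further here, with tests on the clock chosen after the result was seen and the split counts planned.

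Clock genes formed 2 opposed sets in both depots. In the higher-series libraries Arntl and Npas2, transcripts of the clock's activating arm, were higher, with series log2 fold changes of 2.55 and 3.27 in BAT and 2.21 and 2.61 in IWAT. Dbp, Per3 and Ciart, which that arm drives, were lower there, with -3.67, -2.51 and -2.69 in BAT and -2.47, -1.55 and -1.84 in IWAT. The median absolute series effect of the 17 clock transcripts was 1.36 in BAT and 1.14 in IWAT, against group effects of 0.225 and 0.379 and medians of 0.359 and 0.193 in random lists. Adjusted over the list alone, 12 clock transcripts in each depot differed between the series with edgeR, against 1 in BAT and 0 in IWAT adjusted over all genes. Both higher-series libraries lay beyond the lower-series range on 1 side for 11 BAT and 12 IWAT clock transcripts, where chance gives 13.3%. The series effects correlated between depots (r = 0.928 across the 17 transcripts, which are not independent). Higher-series files carry the same numbers in both depots, so this correlation may rest on the same animals.

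IWAT libraries also carried traces of other tissues. The mammary and skin transcripts Csn3, Krt14 and Krt5 stood at 16.1, 6.67 and 3.50 CPM in WT-NC replicate 2 and at 0 in every other IWAT library, except Krt14 at 0.258 CPM in KI-HFD replicate 2. The summed epithelial and mammary transcripts stood at 137 CPM in WT-NC replicate 2 and at 9.27 to 41.4 CPM in the other IWAT libraries. These genes were chosen after their values were seen. The summed T and natural killer cell transcripts stood at 603 CPM in KI-HFD replicate 3 and at most 130 CPM in the other IWAT libraries.

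For each depot the 6 libraries make 10 splits, the real one included, too few for a share under 0.05. In BAT the real split gave 7 genes with edgeR and the highest other 1, and 23 lists with the highest other 22. Counting the real split itself, 1 split was as large for each. In IWAT the real split gave 0 genes and the highest other 0, and 17 lists with the highest other 24. Counting the real split itself, 10 splits were as large for genes, which a real count of 0 fixes, and 6 for lists. With DESeq2 another split gave 635 genes in BAT against the real 244, and 573 in IWAT against the real 349 (2 splits as large in each, the real one included). Both of these splits put the 2 higher-series libraries of the depot on the same side. The other 3 splits that do so gave 28, 1 and 34 genes in BAT and 6, 3 and 24 in IWAT, and a BAT split that divides the series gave 110, so the series alone does not set these counts. With that series as a batch term edgeR called 0 genes in each depot, with 2069 BAT and 1908 IWAT genes at an unadjusted p under 0.05, and camera called 22 and 17 lists. The log2 fold changes of the 7 BAT genes barely moved with it, as for Spp1 with -3.48 in each fit (SE 0.373 without and 0.369 with the term). Within the lower series alone camera called 21 lists in each depot.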
